A study of Homo sapiens with 6 samples.

How the data were processed

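RNA sequencing was done on KMS-27, a human multiple myeloma cell line, after transfection with a control siRNA (siControl) or with an siRNA against Che-1, the protein encoded by AATF (siChe-1). Per the labels, each group had 3 libraries, made from 500 ng of total RNA with a stranded total RNA kit after removal of ribosomal RNA. External RNA controls (ERCC spike-ins) of known sequence had been added. Nothing in the labels says at which step, or how much. Groups and replicate numbers were taken from the sample titles.

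Deposited tables of 3 kinds were used. The first gives the raw count of reads for 92 spike-ins in each of the 6 libraries, per the file headers. The second is a table of the authors' own comparison, per the file headers: for 16444 genes it holds a signal, which is the authors' read count divided by each library's spike-in size factor and averaged over a group, with the authors' ratio (fold change), its log2, and a p-value with an adjusted p. The third lists 18750 transcripts with the authors' group FPKM (fragments per kilobase of transcript, scaled to library size), 3 FPKM values per group that belong to its libraries but carry no replicate number, the authors' log2 of the group ratio, and p and q values, per the file headers. Every transcript in it has the status OK. TopHat, Cufflinks, Cuffdiff, HTSeq and DESeq2 were used on the human build hg19, per the submitters' processing notes, which give neither versions nor roles. Whether counting used the strand is not given in the sources used here.

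The libraries behind the authors' signal were worked out from its values. The overall mean weighed siControl by 0.6 in each of the 15717 genes whose groups differed, which is 3 of 5 libraries. Low group means (1327 in siControl and 2139 in siChe-1, all below 3) were then tested against whole reads divided by spike-in size factors. With siChe-1 replicates 1 and 2 and factors from these 5 libraries, 100% of both were whole-read sums, to a relative tolerance of 8e-15, and with any other set of siChe-1 libraries 0% were. siChe-1 replicate 3 is therefore not in that table, although its spike-in reads are in the first. Whole reads per library were recovered for 16321 of the 16444 genes (99.3%). The other 123 genes, all abundant, allow more than 1 set of reads and hold 19.7% of the normalized siControl reads and 18.8% of the siChe-1 reads. Among 1500 genes of simulated reads, 99% were recovered right and 0% wrong, and none of the values shifted at random gave whole reads.

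The authors' adjusted p was counted in their comparison table, among genes with a mean of at least 10. The recovered reads of 5 libraries were tested with edgeR's quasi-likelihood test on the authors' spike-in size factors, with the same minimum. For changes relative to other genes, the FPKM values of all 6 libraries were used. Transcripts on assembled chromosomes were summed by gene, giving 12075 genes. Genes with a mean FPKM of at least 10 were kept (6285), the libraries were rescaled by the median of ratios over these genes, and log2(FPKM + 1) was tested with limma with a mean-variance trend. Folds on that scale understate the change of low genes. All p-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Gene lists, 24 in all, were fixed before the data were examined, and the 19 with at least 5 tested members were compared with the other genes by camera with a preset correlation of 0.01. Values per library were compared by exact permutation tests. These double the smaller tail, so that with 3 libraries against 2 the smallest two-sided p is 0.2. The labels do not say that libraries of a group came from separate cultures, so that p-values measure only the spread between these libraries, which may be technical.

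The planned design had tested per-library spike-in values of 6 libraries. Since the table holds the authors' means of 5, their adjusted p was counted, as planned for that case, and the list tests moved to FPKM. The order of filter and rescaling, and the return from a minimum FPKM of 1 to the planned 10, were settled after the counts under each had been seen.

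Named genes followed a rule fixed before the data were examined. It takes AATF, a panel of 12 genes, and the 5 largest falls and rises on each scale among called genes with no overlap between the groups' libraries (mean of at least 100, or FPKM of at least 5 in a group). Of each list it takes the 2 members with the smallest p and the most abundant member. Of lists of other cell types, the most abundant member is named. The genes called higher in the authors' table and the MHC class II genes were named after their values were seen.

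Tests were tried on simulated data with 200 changed genes. limma on FPKM (6285 genes) recovered 25% of changes of 0.5 on the log2 scale and 88.5% of changes of 1, with 1 and 2 false calls. edgeR on the spike-in scale (12468 genes) recovered 0% and 25%, with 0 false calls at either size. camera called 1% of the random lists and 100% of the lists of 40 genes shifted by 0.2, among 6285 genes. Simulated genes varied independently in all of these, so that the rates do not cover noise shared between genes. In the called lists the estimated correlation between genes ran from 0.16 for ribosome biogenesis to 0.54 for glycolysis and hypoxia, above the preset 0.01. The replicate pairs among the 5 libraries with recovered reads differed by more than sampling noise, with a chi-square per gene between 7.44 and 21.5, so none of these was a copy of another of its group. siChe-1 replicate 3 could not be checked this way.

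Alternatives covered the filter, pseudocount, scaling, tool, threshold, each library left out, the replicate number or list position as a block, and a correction for GC content and transcript length, taken from GENCODE release 29 transcripts for 92.3% of the tested genes. Coordinates are those of the deposited hg19 transcripts, counted from 1. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. DESeq2 served as an alternative on the recovered reads.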

Results

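Transcription in KMS-27 myeloma cells was compared between siControl and siChe-1, with 3 libraries each. Che-1, encoded by AATF, is an RNA polymerase II-binding protein with a further role in ribosome assembly in the nucleolus. The title of the series speaks of growth and global transcription, so that the change of all genes against the spike-ins comes before the change of single genes relative to the rest. The 5 libraries of the authors' spike-in table held 19169774 to 21780505 recovered gene reads. The read depth of siChe-1 replicate 3, which is not in that table, is unknown.

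AATF itself, on chromosome 17 from 35306175 to 35414171 on the plus strand of hg19, was low in every siChe-1 library. Its spike-in-normalized reads were 7157, 9855 and 10905 in siControl replicates 1 to 3 (mean 9306 ± 1933, SD, n = 3) and 672 and 549 in siChe-1 replicates 1 and 2. The authors' deposited table gives a log2 fold change of -3.93 with an adjusted p of 1.56e-13. edgeR's quasi-likelihood test on the recovered reads gave -3.93 ± 0.38 (SE), adjusted p 1.69e-21. In FPKM, which covers all 6 libraries, AATF stood at 97.0, 88.8 and 119 in siControl (mean 102 ± 15.5, SD, n = 3) and at 14.2, 14.2 and 16.9 in siChe-1 (15.1 ± 1.57, SD, n = 3). Relative to other genes it fell by 2.57 ± 0.11 (SE) on the log2(FPKM + 1) scale (limma adjusted p 0.000117).

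Against the spike-ins, nearly all genes were lower in the siChe-1 libraries of the authors' table. Among the 12591 genes with a mean of at least 10 in the authors' deposited table, the median log2 fold change was -1.25, with quartiles of -1.51 and -0.97, and 98.4% of the genes had a negative value. Of these genes, 8009 in the authors' deposited table passed an adjusted p of 0.05, 8001 of them lower and 8 higher. In the authors' deposited table the log2 fold change was -1.33 for IRF4 and -1.40 for PRDM1, transcription factors of plasma cells, -1.37 for POLR2A, the largest subunit of RNA polymerase II, -1.19 for ACTB and -1.62 for GAPDH, each with an adjusted p under the threshold.

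The libraries behind this shift differed among themselves. Gene reads per spike-in read were 38.8, 56.7 and 57.9 in siControl (mean 51.1 ± 10.7, SD, n = 3). They were 22.9 and 19.4 in siChe-1 replicates 1 and 2 (mean 21.2). The difference was 2.41-fold (exact permutation test, two-sided p = 0.2, the smallest this test allows here). The median gene lay at -0.41, 0.18 and 0.15 in the siControl libraries against the siControl mean (log2), and at -1.12 and -1.37 in those of siChe-1 (exact permutation p = 0.2). Spike-in reads numbered 519573, 351573 and 376170 in siControl and 835414, 1041244 and 379232 in siChe-1, so that siChe-1 replicate 3, the library left out of the authors' table, had as few as the controls (exact permutation test over 6 libraries, two-sided p = 0.2). At the depth of the other libraries it would have 50.5 to 57.4 gene reads per spike-in read, within the range of siControl. Its own gene reads are not in the tables used here.

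**Figure D1:**
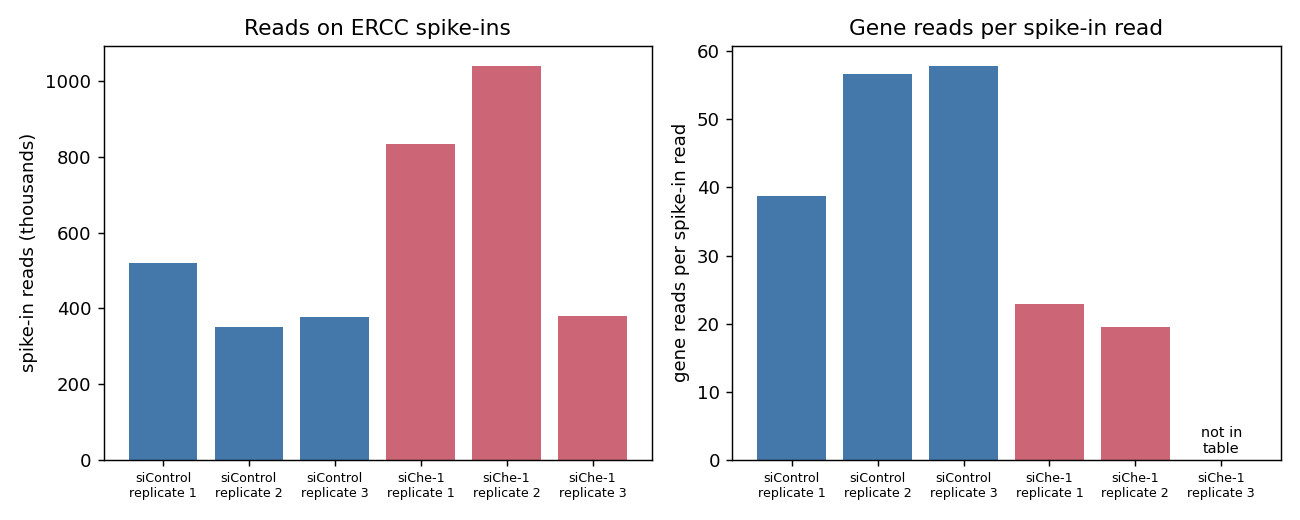
Left, reads on ERCC spike-ins; right, recovered gene reads per spike-in read, with each bar a library and siChe-1 replicate 3 missing at right because the authors' table leaves it out. siChe-1 replicates 1 and 2 have 22.9 and 19.4 gene reads per spike-in read, below the 38.8 to 57.9 of siControl, while siChe-1 replicate 3 has 379232 spike-in reads.

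edgeR on the recovered reads called 10545 of 12482 genes on the spike-in scale, 24 higher and 10521 lower. Each library's spike-in scale is shared by all its genes, here and in the authors' comparison. These calls therefore largely restate a single shift between 3 libraries and 2. The p-values of genes on this scale, that of AATF included, treat the shared error as if each gene had its own. Rescaled on the genes themselves with TMM, the same reads gave 3640 calls, 1760 higher and 1880 lower, and a median change of 0.000340. The median of ratios gave 1701 higher and 1945 lower, and the upper quartile 1926 higher and 1676 lower. Without siChe-1 replicate 2, 2825 genes were called on the spike-in scale, 4 higher and 2821 lower.

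The largest falls on the spike-in scale after AATF were in C2orf54 (chromosome 2, 241825465 to 241835573), GABRB2, a GABA receptor subunit, CXCL10, an interferon-induced chemokine, and SCARB1, a receptor for high-density lipoprotein. In the authors' deposited table their log2 fold changes were -3.53, -3.53, -3.42 and -3.35. Only CIITA, the transactivator of MHC class II genes, and SLC2A3, a glucose transporter, were higher in the authors' deposited table and met the rule for named genes, by 0.99 (adjusted p 0.0429) and 0.98 (adjusted p 0.0383). The other 6 genes called higher in the authors' deposited table, named after their values were seen, were GBP4, NAV2, XAF1, FCER2, CEACAM1 and LILRB4, with log2 fold changes from 1.40 for NAV2 to 2.83 for FCER2 at group means under 100.

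Relative to other genes, the FPKM of 6 libraries changed in both directions. limma called 1897 of 6285 genes, 949 higher and 948 lower, of which 73 changed at least 2-fold. Leaving out a library lowered the calls to as few as 984, without the siChe-1 library at list position 3. With the deposited scaling the split was 592 higher and 1279 lower, with rescaling over all genes before the filter 634 and 1207, and with the upper quartile 1221 and 713. The largest falls after AATF were in C2orf54 (-2.02 ± 0.17, SE), STS, steroid sulfatase (-1.70 ± 0.08), COL18A1, a collagen (-1.58 ± 0.21), and PCCB, a subunit of propionyl-CoA carboxylase (-1.57 ± 0.10). The largest rises were in FCRLA, an Fc receptor-like protein of B cells (1.94 ± 0.13), CD74, the invariant chain of MHC class II (1.56 ± 0.10), C8orf83 (1.44 ± 0.09), CPQ, a carboxypeptidase (1.40 ± 0.10), and EMP3, a membrane protein (1.38 ± 0.18). The limma adjusted p of these 9 genes lay between 0.000142 for STS and 0.00232 for COL18A1.

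**Figure D2:**
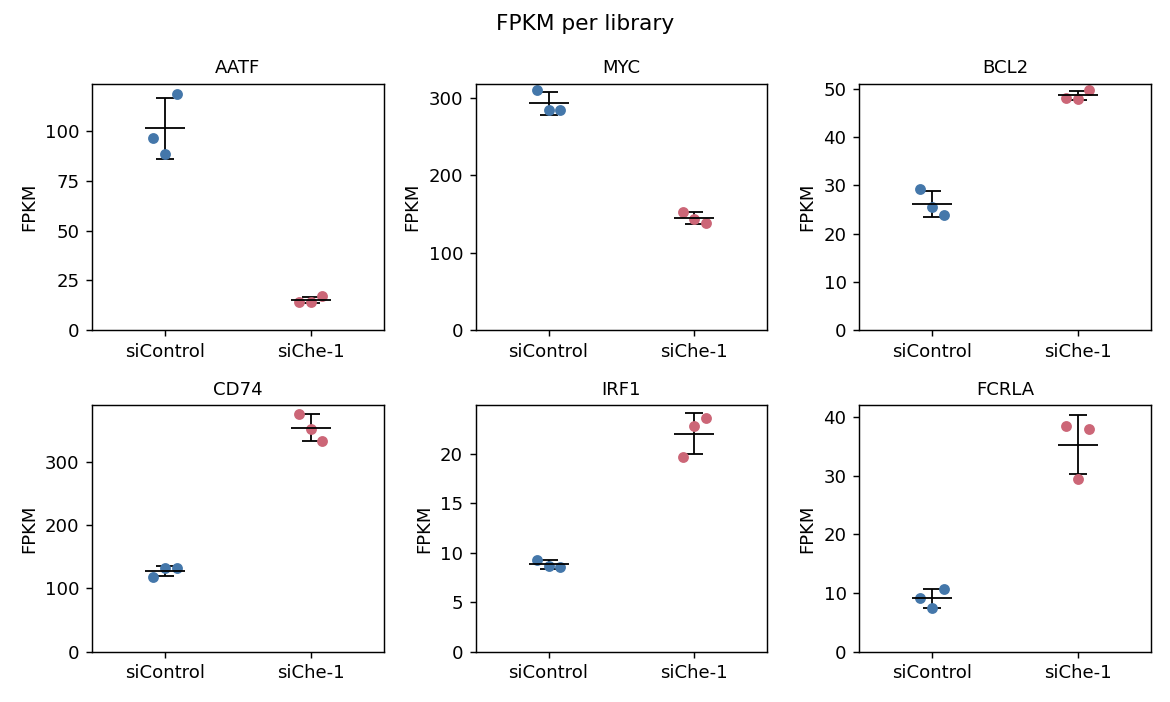
FPKM of 6 genes in the 3 libraries of each group (points), with the mean and SD as bars. AATF falls from 102 to 15.1 and MYC from 293 to 145, while CD74 is at 127 in siControl and 353 in siChe-1; FPKM is scaled to each library's own reads and does not show the shift against the spike-ins.

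Not all of these calls hold on both scales. FCRLA and CD74 were at 0.72 and 0.36 (log2) in the authors' deposited table, with adjusted p of 0.119 and 0.508, and neither was called there. edgeR on the recovered reads did call FCRLA higher on the spike-in scale (edgeR adjusted p 0.0408). It did not call CD74 (edgeR adjusted p 0.254), C8orf83 (0.793), CPQ (0.629) or EMP3 (0.947). From here on, rises and falls of genes and lists are relative to other genes, unless the spike-ins or the authors' deposited table are named. A gene that rose on that relative scale can still be lower against the spike-ins. Of the genes tested in both, 1448 were called on FPKM and with TMM on the recovered reads, 1447 of them in 1 direction. The 5 libraries of the recovered reads are among the 6 of the FPKM table, so that this overlap is no independent repeat.

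Ribosome biogenesis factors were lower as a list. Relative to other genes, 35 of 53 tested members were lower and 0 higher, and adjusted over the list alone 40 were lower. The list's median lay 0.44 below that of all tested genes on the log2 scale (difference -0.44, camera adjusted p 1.14e-12, adjusted p = 0.622 with an estimated correlation). WDR3 and NOL10, both of the small-subunit processome, fell by 0.69 and 0.56, and NPM1, the abundant nucleolar phosphoprotein, fell by 0.61 from an FPKM of 2114 ± 345 to 1286 ± 108 (SD, n = 3). In the authors' deposited table all 55 members were called lower, with a median of -1.77. Of all 12591 genes there, 8001 were called lower, and the median of all was -1.25. The list's difference was at most 0.18 under the other splits of the 6 libraries, although camera called it in 7 of these 9. Each other split mixes the groups unevenly, so that part of a group difference stays in it. For this and the other lists, these splits are therefore no measure of chance alone.

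Glycolysis and hypoxia genes were lower as a list, and few respiratory chain genes were called. Of 19 glycolysis and hypoxia genes, 9 were lower and 1 higher (9 and 1 adjusted over the list alone), with a difference of -0.33 (camera adjusted p 0.00238, adjusted p = 0.622 with an estimated correlation). HK2, the hexokinase of the first step of glycolysis, fell by 0.84, PKM2 by 0.54 and GAPDH by 0.33, the last losing its call in 9 of 19 other settings. On recovered reads on the spike-in scale this list was not called (adjusted p 0.234). Of 43 respiratory chain genes 6 were lower and 0 higher (2 adjusted over the list alone), with a difference of -0.20 (camera adjusted p 0.00238, adjusted p = 0.622 with an estimated correlation). NDUFA10 and NDUFB9, subunits of complex I, fell by 0.75 and 0.48, each losing its call with 1 library left out, and UQCRH of complex III fell by 0.32, a call lost in 9 of 19 other settings. After correction for GC content and length the difference was -0.13, adjusted p 0.0605. Under the other splits of the libraries the glycolysis list differed by up to 0.30 and the respiratory chain by up to 0.17, and camera called them in 5 and 4 of 9.

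Ribosomal protein and histone genes moved little. Of 73 ribosomal protein genes 4 were lower (0 adjusted over the list alone), with a difference of -0.12 (camera adjusted p 0.00553, adjusted p = 0.622 with an estimated correlation). RPL23 fell by 0.44 and RPL14 by 0.40, calls lost in 4 and 5 of 19 other settings, and RPS27 was at 0.27 with an adjusted p of 0.243 by limma. Of 47 replication-dependent histone genes 2 were lower, HIST1H4I by 0.69 and HIST2H2AC by 0.49 (1 adjusted over the list alone), the latter losing its call in 7 of 19 other settings, and HIST1H2AJ was at -0.01 ± 0.40 (SE). The histone list's difference was -0.15 (camera adjusted p 0.0266, adjusted p = 0.797 with an estimated correlation). Neither list was called after correction for GC content and length (adjusted p 0.287 and 0.481), and another split of the libraries gave a larger difference for each, 0.17 and 0.27, with calls in 3 and 6 of 9. Ribosomal proteins and histones have near-identical gene copies or pseudogenes, so that their single values are uncertain.

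Immediate early and interferon-stimulated genes were higher as lists relative to other genes. Of 13 immediate early genes, whose mRNAs are short-lived, 8 were higher and 1, MYC, was lower (9 and 1 adjusted over the list alone), with a difference of 0.43 (camera adjusted p 0.00466, adjusted p = 0.622 with an estimated correlation). IER5 rose by 1.07 ± 0.13 (SE). MYC, on chromosome 8 from 128748315 to 128753680, fell by 0.92 ± 0.10 (SE, limma adjusted p 0.00109), and by 2.16 in the authors' deposited table. Of 7 interferon-stimulated genes 4 were higher and 0 lower (5 adjusted over the list alone), with a difference of 0.33 (camera adjusted p 0.00469, adjusted p = 0.622 with an estimated correlation). IRF1, an interferon-responsive transcription factor, rose by 1.31 and IFIH1, a sensor of double-stranded RNA, by 0.76, while BST2 was at 0.26 with a limma adjusted p of 0.238. At a minimum FPKM of 1, chosen after seeing the data, 23 members were tested, with a difference of 0.61 (camera adjusted p 5.52e-09). The 29 measured members of this list had a median of -0.23 in the authors' deposited table, 3 being called lower and 1 higher. CXCL10, named above for its fall, is itself induced by interferon. Under the other splits each of these lists differed by up to 0.25, with calls in 4 and 2 of 9.

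**Figure D3:**
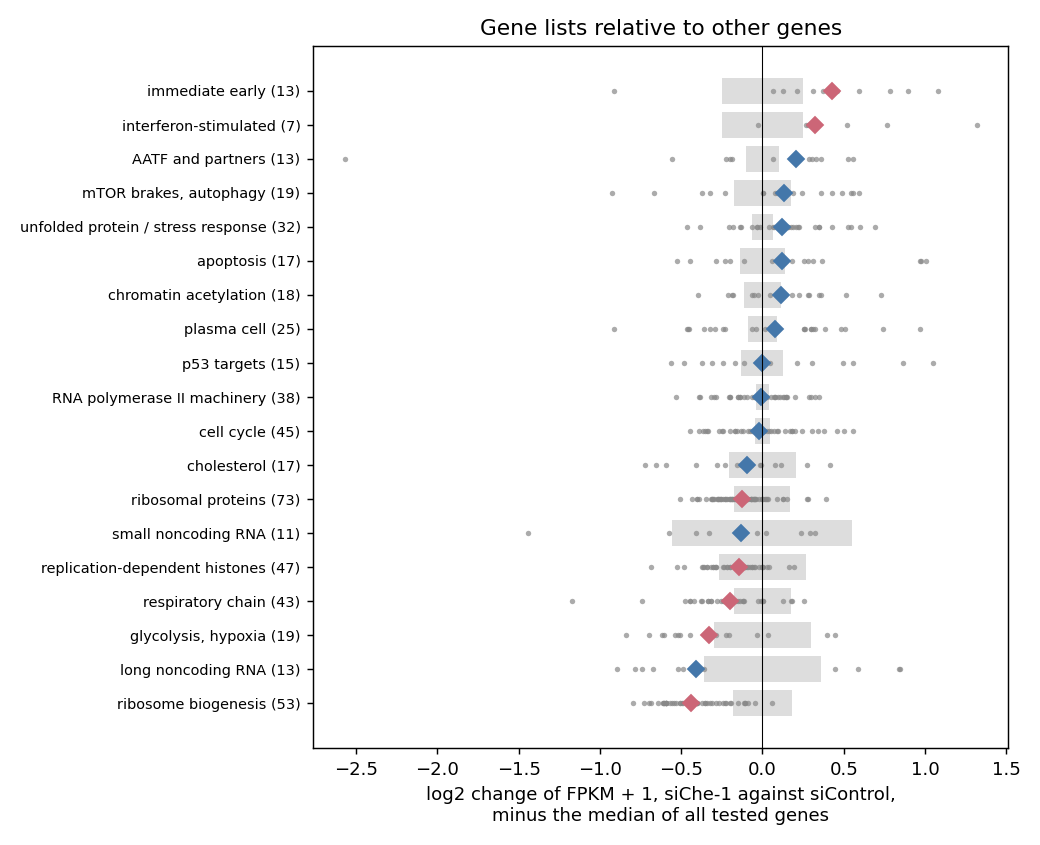
Change of each gene list relative to other genes, log2 of FPKM + 1 minus the median of all tested genes, with small points for members and diamonds for the list's median (red where camera's adjusted p is under 0.05, blue otherwise). Grey bands reach to the largest median difference under the other splits of the 6 libraries, which is 0.18 for ribosome biogenesis against its -0.44. These splits still hold part of any group difference, so that the bands are no range of chance. Numbers in brackets are tested members.

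The plasma cell list did not move as a whole (difference 0.08, camera adjusted p 0.767), with 6 of 25 members higher and 7 lower (9 and 7 adjusted over the list alone). BCL2, the anti-apoptotic protein, rose by 0.97, from an FPKM of 26.2 ± 2.74 to 48.7 ± 0.99 (SD, n = 3), and XBP1, a driver of the secretory program, fell by 0.47, a call lost in 4 of 19 other settings. MYC, also a member of this list, fell by 0.92. IRF4 (0.01 ± 0.09), PRDM1 (-0.04 ± 0.08) and the immunoglobulin joining chain IGJ (0.26 ± 0.19) were not called (limma adjusted p 0.944, 0.719 and 0.350). On the spike-in scale BCL2 was at -0.33 in the authors' deposited table, adjusted p 0.552.

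AATF and its partners had 5 of 13 members higher and 2 lower (6 and 2 adjusted over the list alone), with a difference of 0.21 and a camera adjusted p of 0.709. The list's median lay above and its mean below that of other genes, at 0.21 and -0.08, AATF itself being a member. The 2 lower members were AATF and NOL10, which fell by 0.56 (limma adjusted p 0.00187). HDAC1, a histone deacetylase, rose by 0.36 relative to other genes (limma adjusted p 0.0231), a call lost in 6 of 19 other settings. In the authors' deposited table HDAC1 was called lower, at -0.98 (adjusted p 0.0370). Of the brakes on mTOR and autophagy genes 5 of 19 were higher and 3 lower, alike adjusted over the list alone (camera adjusted p 0.291). DEPTOR, an mTOR inhibitor abundant in myeloma, fell by 0.67 and ATG5, of autophagosome formation, by 0.93, while GABARAP rose by 0.59. DDIT4 (REDD1) was at 0.14 ± 0.14 with a limma adjusted p of 0.465, and SQSTM1 at 0.00 ± 0.09.

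Stress and death genes were not called as lists, and their members went both ways. For comparison with the counts per list, 1897 of all 6285 tested genes were called. Of 17 apoptosis genes 5 were higher and 2 lower, alike adjusted over the list alone (camera adjusted p 0.244). The pro-apoptotic BH3-only genes BMF and PMAIP1 rose relative to other genes (limma adjusted p 0.000820 and 0.00187), BMF by 0.97. The anti-apoptotic BCL2, also on this list, rose by 0.97 too (limma adjusted p 0.000892). Of 15 p53 targets 4 were higher and 3 lower (5 and 3 adjusted over the list alone, camera adjusted p 0.767), TP53INP1 rising by 1.04 and TRIAP1 falling by 0.49, with CCNG1 at -0.25 and MDM2 at 0.30 not called. CDKN1A, the cell cycle inhibitor p21, was below the FPKM minimum, at 1.26 ± 1.12 in siControl and 5.08 ± 0.49 in siChe-1 (SD, n = 3), with 1 siControl value near 0 although each siControl library held 113 to 194 normalized reads. In the authors' deposited table CDKN1A was at 0.50, not called (adjusted p 0.298). Of 32 genes of the unfolded protein and stress responses 3 were higher and 2 lower, alike adjusted over the list alone (camera adjusted p 0.170). PPP1R15A and DDIT3, both of the integrated stress response, rose by 0.69 and 0.59, with the chaperone CANX at -0.21 not called.

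Cell cycle genes moved little, with 4 of 45 higher and 5 lower (3 and 3 adjusted over the list alone, camera adjusted p 0.767). KIF11, a spindle motor, rose by 0.50, CCNB1 fell by 0.45, a call lost in 2 of 19 other settings, and TOP2A was at 0.24 with a limma adjusted p of 0.103. Of 38 genes of the RNA polymerase II machinery 2 were higher and 2 lower (0 and 1 adjusted over the list alone, camera adjusted p 0.767). GTF2F2, a TFIIF subunit, fell by 0.53, TAF1 rose by 0.34, a call lost in 9 of 18 other settings, and POLR2K was at 0.20, not called. Of 18 genes of chromatin acetylation 6 were higher and 1 lower, alike adjusted over the list alone (camera adjusted p 0.201), among them KAT7 and HDAC6, which rose by 0.51 and 0.72.

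Noncoding RNAs and cholesterol genes were not called as lists. Of 13 long noncoding RNAs 3 were higher and 8 lower, alike adjusted over the list alone (difference -0.41, camera adjusted p 0.201), TUG1 rising by 0.83, DANCR falling by 0.90 and MALAT1 at 0.44 not called. Of 11 short structured RNAs 1 was lower and 0 adjusted over the list alone (camera adjusted p 0.709). RMRP, the RNA of RNase MRP, was at -0.41, a call lost in 12 of 19 other settings, and SCARNA7 at -0.33, not called. Of 17 cholesterol genes 1 was higher and 4 lower, alike adjusted over the list alone (camera adjusted p 0.201), EBP falling by 0.60 and DHCR7 by 0.66, with CYP51A1 at -0.01 not called. At a minimum FPKM of 1, chosen after seeing the data, the cholesterol list was called lower (difference -0.14, camera adjusted p 0.0473).

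The most abundant markers of other marrow cells stood below the middle of all genes, from percentile 27.2 for CD3G to 47.3 for LEPR. The most abundant marker of myeloid cells, CD68, had a mean of 81.7 normalized reads in the authors' deposited table, that of T and NK cells, CD3G, 19.1, that of stroma and endothelium, LEPR, 269, and that of erythroid cells, HBD, 116. HBD fell in the authors' deposited table, from 169 to 35.1, adjusted p 0.000396, and the other 3 were not called. Of the mitochondrial genome, 0 listed genes were measured.

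The FPKM table carries the authors' own calls, which ask the same question without spike-ins. The authors' deposited table marks 3430 of 18750 transcripts as significant, 1510 higher and 1920 lower in siChe-1, among them AATF at a log2 of -2.75 with q = 0.000601. Its smallest p, 5e-05, is shared by 1559 transcripts. Matched by gene symbol to the spike-in comparison, 53.1% of 18456 transcripts had the same sign in both of the authors' deposited tables, and 81.0% after each table's median was subtracted. Across these transcripts, which are not independent replicates, Spearman's rho was 0.69 and Pearson's r 0.36, and 0.92 and 0.79 across the 7919 symbols found once in each table. Of the 18456 transcripts, both of the authors' deposited tables called 1984, fewer than the 2350 that independent lists would share. A gene's spike-in call counts there for each of its transcripts, and across the 7919 symbols these values were 1364 and 1513. Of the 1984, 1871 were lower in both and 109 were higher in FPKM yet lower against the spike-ins. The FPKM calls were 1477 higher and 1912 lower, so that the shortfall lies in those called higher.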

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

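On FPKM, the minimum of 1 or, for single genes, 50, the scaling as deposited, the rescaling over all genes before the filter, the correction for GC content and length, the block on list position, the stricter thresholds, the pseudocounts for single genes and limma without trend or robust were chosen after seeing the data, and so was the replicate block with TMM for the spike-in results. AATF kept its fall in all 20 settings of its change against the spike-ins, rescaled ones included, from -4.09 to -2.57, and in the 19 of its change relative to other genes, from -2.66 to -2.32. Gene signal per spike-in read kept its direction in 9 settings, and the median log2 fold change stayed between -1.41 and -1.12 in 14 settings on the spike-in scale. Rescaling on the genes themselves removes that median by construction, leaving -0.00941 with the median of ratios, 0.0279 with the upper quartile, 0.000340 with TMM, -0.00147 with TMM and the replicate block, and -0.0947 in FPKM as deposited. At an adjusted p under 0.01 the authors' deposited table holds 4620 genes. On recovered reads the calls went from 10545 to 3646 with the median of ratios, 3602 with the upper quartile and 3640 with TMM, and ranged from 2825 to 11676 with a library left out, where a lone siChe-1 library is assumed to vary like the others. The replicate block gave 58 calls, and 3912 with TMM. Same-numbered deviations correlated at 0.40 in each of the 2 pairs complete in these reads, which are too few to settle whether the numbers pair the libraries, and no pairing was used. With only 2 siChe-1 libraries, their deviations mirror each other, so that these values are not separate. In the FPKM lists, which carry no numbers, same positions correlated at 0.40, 0.66 and 0.18. But siChe-1 position 3 did so more with siControl position 1 (0.26), as a hint only. The trend with GC content was alike in siControl and siChe-1 at position 1 (rho -0.58 and -0.56) and position 2 (0.43 and 0.54). At position 3 it was not (0.11 and -0.11).

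Relative to other genes, the calls went from 1897 to 3044 with no filter, 2934 at a minimum FPKM of 1 and 407 at 50, where fewer genes were tested. They were 792 at an adjusted p under 0.01, 510 at a fold of at least 1.5 and 73 at 2, 3631 with a block on list position and 3482 with that block and the correction for GC content and length, 3640 with TMM on recovered reads and 3912 with the replicate block there. Leaving out a library gave 984 to 1743. The authors' FPKM calls went from 3430 to 528 at a fold of at least 2, and the share of the same sign from 53.1% to 81.0% with each table's median subtracted, which moves the point where signs are split. Of the lists, 7 were called, against 1 at a minimum of 50, 4 with the correction for GC content and length, 4 with that correction on recovered reads, 2 with fry, which tests against no change and not against other genes, and 0 by camera with an estimated correlation. Except where given above, the cause was not tested. Among single genes and lists, 1577 alternatives left the call as it was, 102 lost a call and 22 gained 1. RMRP lost its call in 12 settings, GAPDH, TAF1 and UQCRH in 9 each. TOP2A gained a call in 4 settings, BST2 in 3 and the cholesterol list in 2. Settings that change pseudocount, scaling or libraries could not be run on the authors' own calls, and were run on recovered reads. Depth limits genes with few reads, such as FCER2 with a siControl mean of 4.26 in the authors' deposited table.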

Other observations

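Genes of MHC class II were looked at because CIITA and CD74 had been seen to be higher, so that the group is no independent evidence and was not tested as a list. Without these genes, 6 of 8 measured members were higher relative to other genes and 0 lower, with TMM on the recovered reads, at a median of 1.41. HLA-DRA, an alpha chain, was at 2.27 ± 0.30 (SE, edgeR adjusted p 0.000192), HLA-DPB1 at 2.05 ± 0.25 (edgeR adjusted p 9.55e-05) and HLA-DQA1 at 1.22 ± 0.20 (edgeR adjusted p 0.000813), all from fewer than 200 normalized reads. RFX5, which binds MHC class II promoters, was at -0.19, not called. Against the spike-ins only CIITA was called higher in the authors' deposited table. Reads shared between HLA paralogs leave the single values uncertain.

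For the shift against the spike-ins, the test of unequal spike-in amounts was chosen only after the result was seen, and so was the siControl value of the noise test. A lower depth of siChe-1 replicate 3 could hide the same fall there, if it had 40.8% of the reads of the other siChe-1 libraries. Excess counting noise in low genes ranged over 0.045 between the siChe-1 list positions, where that depth predicts 0.0325 to 0.0757 and equal depth up to 0.0249. The siControl positions, not at issue, ranged over 0.047, so this test cannot tell. Unequal amounts of spike-in RNA could likewise give the shift: the lowest siControl library exceeded the highest siChe-1 library 1.69-fold, and siControl libraries differed up to 1.49-fold, but without replicate 3 this cannot tell either.

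For the genes called relative to the rest, the test of splits was chosen only after the result was seen. Of the 10 splits of the 6 libraries, 1, the real grouping, gave 1897 genes, and the highest other gave 1. For lists, where the prediction came first, again 1 of 10 splits gave as many as the 7 called, with 6 in the highest other. With 10 splits no share under 0.05 is possible, and for lists the other splits came close. Each other split mixes the groups unevenly, so that part of a group difference stays in it and part adds to its spread. None therefore measures chance alone.

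For the lists that were lower, set tests corrected for GC content and length, and percentiles matched on expression, were seen before the predictions were written. Among lists matched on length, GC content and expression, ribosome biogenesis stood at percentile 0 and glycolysis at 0.12, so that length and GC content are not likely to be the whole cause. The respiratory chain stood at 8.99, ribosomal proteins at 78.3 and histones at 44.7, values that length, GC content and expression together could give. Matched on expression alone they stood at 2.29, 67.2 and 27.9. For ribosomal proteins and histones, expression alone could thus give such values, and the part of length and GC content is not separated. Longer transcripts rose relative to short ones (Spearman's rho 0.22 across genes). Single libraries had trends as large, from -0.22 to 0.33 in siControl and from -0.23 to 0.22 in siChe-1. The median histone transcript has 438 bases against 3571 for all tested genes. Length was that of the longest annotated transcript of each gene, which need not be the one expressed. The biological explanation, silencing of Che-1, has the same grouping and was not separately tested.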
